A study of Homo sapiens with 6 samples.

How the data were processed

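The deposited values, 1 intensity for each of 54675 probe sets on each of 6 arrays, were used as the authors gave them. They were linear, with the lowest value of an array between 3.12 and 3.44, and log2(intensity + 1) was taken. The added 1 makes log2 changes of dim genes smaller than their fold changes. Per the series' design text the values were processed by "RAMA", and neither a method nor a version was given in the sources used here. Whether the word names a package or is a spelling of RMA was not stated. The labels name no genome build. No further normalization was applied.

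Of the probe sets, 41097 carried exactly 1 gene symbol, 1801 several and 11777 none, and only the first kind was used. Current names came from a table of RefSeq genes on assembly GRCh38, through the Entrez number for 41043 probe sets, and that table was used only for names and for which genes neighbour each other. Each of 19775 genes was represented by its brightest probe set over all 6 arrays. Genes at or above the 40th percentile of all probe set means (log2 3.66, intensity 11.7) were kept, which left 14875.

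Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group and a spread shared by all 3 groups (3 residual and 4.81 prior degrees of freedom). The contrasts were the mean of both shRNA groups minus shLuc, each shRNA minus shLuc, and shHP1γ-17 minus shHP1γ-16. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The p-values of single genes measure spread between these samples, 2 per group, and the number of arrays limits their precision. Genes shared by the shRNAs passed with the same sign in each single contrast. Because both shRNAs were set against the same shLuc arrays, the overlap without any effect was simulated 100 times.

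The samples, the tests of the comparisons, the rule for named genes, 28 gene lists and the alternatives other than the 5' to 3' covariate were set before the data were examined, and the closing section names the tests chosen later. Of the 561 list genes 504 had a named probe set, and lists with at least 5 kept genes were tested, 26 in all. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it, camera with a correlation estimated from the arrays and fry were run. The preset form compares a list's genes with all other genes, so its p-values measure spread among genes rather than between arrays. With an estimated correlation camera rests on the 3 residual degrees of freedom at most. Few lists could pass that form after adjustment, so a miss there says little about a list. Members were also adjusted over their list alone. Genes named were CBX3, CBX1, CBX5, HNRNPA2B1 and ZBTB7A, and a further gene named in advance is not reported here. Also named were the 10 largest rises and falls shared by the shRNAs with all 4 knockdown arrays on the same side of both shLuc arrays, the 5 largest rises and falls of each other comparison, and the 4 members of each list with the smallest p over both shRNAs. Names that only number a locus were left out.

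Fits were repeated with each array left out. A group left with 1 array has no spread of its own, and the lone sample is assumed to vary like the other groups. A covariate for the ratio of 5' to 3' signal of the control probe sets was added after the data were seen. The replicate block was run although the labels give the arrays of different groups only a shared number, and the deviations of arrays with the same number from their group means correlated at 0.358, -0.218 and 0.240.

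The code was run first on simulated values of 14875 genes, of which 200 were changed. For both shRNAs it recovered 0% of changes of log2 0.5, 44.8% of changes of 1 and 98.5% of changes of 2, with 3 calls among unchanged genes. For shHP1γ-16 alone it recovered 0%, 20.9% and 95.5%, and for shHP1γ-17 alone 0%, 23.9% and 97.0%. Far fewer genes were changed there than passed in the data, which makes the adjusted threshold stricter in the simulation. These rates may therefore lie below those in the data.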

Results

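Expression was measured on 6 Affymetrix U133P arrays in H1792 cells, a human lung adenocarcinoma line. The cells had received lentiviral short hairpin RNAs (shRNAs) and 96 hours of selection in puromycin at 1 µg/ml. The 3 groups of 2 arrays each, called biological replicates in the labels, were a control shRNA against luciferase (shLuc) and a pair of shRNAs against HP1γ, shHP1γ-16 and shHP1γ-17. HP1γ, the product of CBX3, is a chromatin protein that binds methylated lysine 9 of histone H3. The median intensity per array was 16.6 on each shLuc array, 16.9 and 16.3 with shHP1γ-16, and 16.3 and 15.9 with shHP1γ-17. Arrays of the same group correlated across the kept genes at 0.984 (shLuc), 0.991 (shHP1γ-16) and 0.987 (shHP1γ-17), and arrays of different groups at 0.955 to 0.975. The control probe sets at the 3' and 5' ends of a transcript differed between groups. The mean ratio of 3' to 5' signal of GAPDH was 1.27 in shLuc, 3.38 with shHP1γ-16 and 1.80 with shHP1γ-17, and that of ACTB was 1.96, 8.58 and 5.10. For dap, a bacterial control transcript, the ratio was 3.51, 14.1 and 5.29. For phe, another bacterial control, it was 2.64, 4.20 and 3.09, and shHP1γ-17 replicate 1 (2.69) lay below shLuc replicate 2 (3.04). Changes below are log2 differences between group means ± their standard error, with 2 arrays per group and adjusted p-values from limma.

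**Figure D1:**
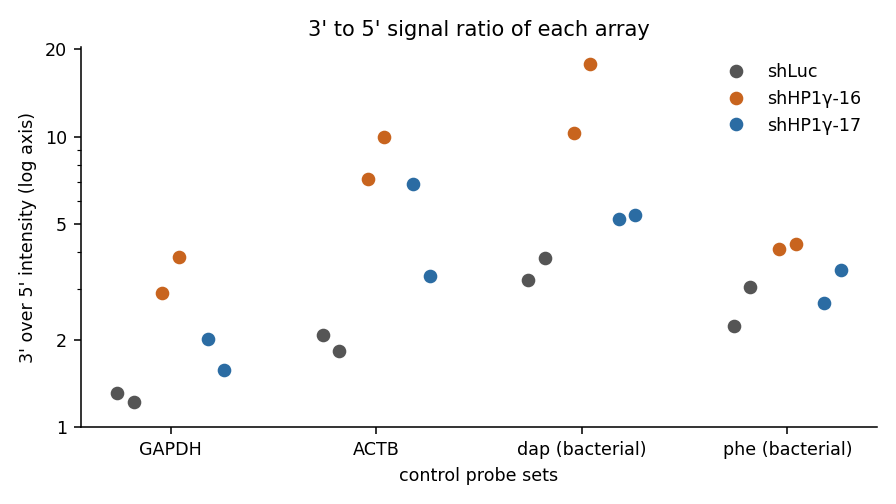
The ratio of 3' to 5' intensity (log axis) is plotted for each array, 1 point per array, for the GAPDH, ACTB, dap and phe control probe sets, with 2 arrays per group. Every knockdown array lies above both shLuc arrays except shHP1γ-17 replicate 1 for phe (2.69).

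CBX3 intensity was 2667 ± 52.0 (SD, n = 2) in shLuc, 282 ± 48.8 with shHP1γ-16 and 95.3 ± 50.6 with shHP1γ-17. CBX3 fell 9.50-fold with shHP1γ-16 (log2 change -3.25 ± 0.34, adjusted p = 0.00342) and 29.9-fold with shHP1γ-17 (-4.90 ± 0.34, adjusted p = 0.000911), and the level differed between the shRNAs (-1.65 ± 0.34, adjusted p = 0.0166). All 4 CBX3 probe sets were lower on every knockdown array than on both shLuc arrays. The next brightest changed by -3.68 with shHP1γ-16 and -4.88 with shHP1γ-17, the other 2 by only -0.93 and -2.13 and by -0.45 and -0.74. The mean over all probe sets gave -2.08 and -3.16, past the threshold with each shRNA. The other HP1 genes, CBX1 for HP1β and CBX5 for HP1α, had changes of 0.10 ± 0.13 (adjusted p = 0.756) and 0.29 ± 0.18 (adjusted p = 0.409) over both shRNAs, neither past the threshold. The 5 other CBX5 probe sets had changes between -0.89 and 0.30. HNRNPA2B1, a splicing factor gene next to CBX3, had a change of -0.09 ± 0.17 (adjusted p = 0.823). Adding the arrays' 5' to 3' signal ratio to the model, a choice made after seeing the data, ended the CBX3 call with each shRNA. The change with shHP1γ-16 was then -1.66 ± 0.92 (adjusted p = 1.00) and with shHP1γ-17 -4.09 ± 0.53 (adjusted p = 0.0843), and 89.6% of the variance of that ratio lay between the groups.

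**Figure D2:**
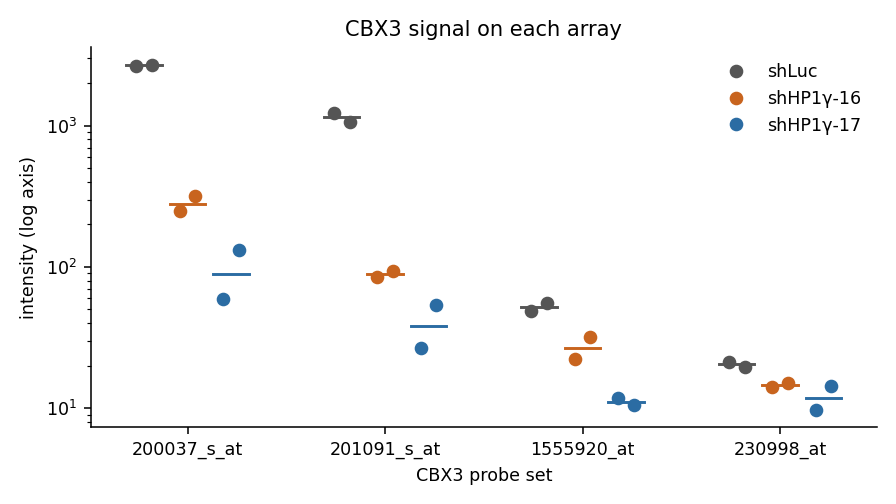
Intensity (log axis) of each CBX3 probe set is plotted for each array, with 2 points per group and a bar at the mean of log2(intensity + 1) turned back to intensity. The brightest probe set went from a mean of 2667 in shLuc to 282 with shHP1γ-16 and 95.3 with shHP1γ-17.

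With both shRNAs against shLuc, the chemokines CCL2 (log2 change 3.67 ± 0.36, adjusted p = 0.00485), CXCL1 (2.92 ± 0.20, adjusted p = 0.00201) and CCL20 (2.57 ± 0.31, adjusted p = 0.00702) rose, as did MMP1, an interstitial collagenase (3.11 ± 0.36, adjusted p = 0.00619). So did SERPIND1, the thrombin inhibitor heparin cofactor II (3.90 ± 0.30, adjusted p = 0.00233), and SERPINB7, another serine protease inhibitor (3.08 ± 0.34, adjusted p = 0.00556). The shLuc intensity of SERPIND1 (6.71) lay below the filter of 11.7, so its change is only approximate. With values raised to the filter it was 3.18. COXFA4L3, which encodes a mitochondrial protein related to a cytochrome c oxidase subunit, rose by 3.67 ± 0.26 (adjusted p = 0.00201), from an intensity of 940 to 16665 with shHP1γ-16 and 7940 with shHP1γ-17. TCIM, a transcription regulator (3.04), ITGA1, a collagen-binding integrin chain (2.78), and PODXL, a cell-surface sialomucin (2.32), also rose, with adjusted p between 0.00233 and 0.0101.

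Beside CBX3, the largest falls were PLAC8 (-3.01 ± 0.15, adjusted p = 0.000824) and AXL, a receptor tyrosine kinase (-2.76 ± 0.26, adjusted p = 0.00485). PKIB, an inhibitor of protein kinase A (-2.51 ± 0.36, adjusted p = 0.0106), KRT80, an epithelial keratin (-2.34 ± 0.22, adjusted p = 0.00485), and ANXA3, an annexin (-2.20 ± 0.15, adjusted p = 0.00201), also fell. CCNA1 (cyclin A1, -2.17), UBE2S, a ubiquitin-conjugating enzyme of the anaphase-promoting complex pathway (-2.16), the neuropeptide gene NMU (-2.14) and TSPAN8, a tetraspanin (-2.12), fell with adjusted p between 0.00485 and 0.0116. ZBTB7A, a transcriptional repressor, rose (1.21 ± 0.15, adjusted p = 0.00752), with shHP1γ-16 by 0.80 ± 0.18 and with shHP1γ-17 by 1.62 ± 0.18. It was named in advance because the published study is known for it, so its rise is not an independent prediction. ZBTB7A passed with both shRNAs in only 2 of the 6 leave-one-out fits. Of its 6 probe sets, the brightest (1.21) and the next brightest (1.13) were higher, and the others had between -0.03 and 0.19. Those others were dim, with mean log2 values of 3.30 to 4.09 against the filter of 3.66, and say little about a change. The mean over all ZBTB7A probe sets, which includes them, did not pass (0.41, adjusted p = 0.0970).

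In all, 1144 of 14875 tested genes passed an adjusted p of 0.05, of which 648 rose and 496 fell. Of these, 449 changed at least 2-fold. The number of arrays limits the precision of this count. It was 305 without shLuc replicate 2, 286 without shHP1γ-16 replicate 1, 182 without shHP1γ-16 replicate 2 and 633 without shHP1γ-17 replicate 1. The named calls of PKIB (without shLuc replicate 2), CCNA1 (without either shHP1γ-16 array) and UBE2S and TSPAN8 (without shHP1γ-16 replicate 2) then missed the threshold at adjusted p from 0.0501 to 0.0612. With the 4 knockdown arrays taken as 1 group, 2 genes passed, PLAC8 the only named gene among them, and with the 5' to 3' ratio in the limma model 0 genes passed, against 378 at an unadjusted p under 0.05. Standard errors then grew by a median factor of 3.09, and the changes correlated with those without it at 0.618. Of the 20 largest changes 7 moved more than 1.5 times, to 1.66 ± 0.86 for MMP1, 1.49 ± 0.75 for SERPINB7, 1.67 ± 0.82 for CCL20, 1.36 ± 0.86 for PODXL, -1.11 ± 0.48 for NMU, -0.27 ± 0.47 for UBE2S and -4.05 ± 0.83 for PKIB. CXCL1 was 2.87 ± 0.62.

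**Figure D3:**
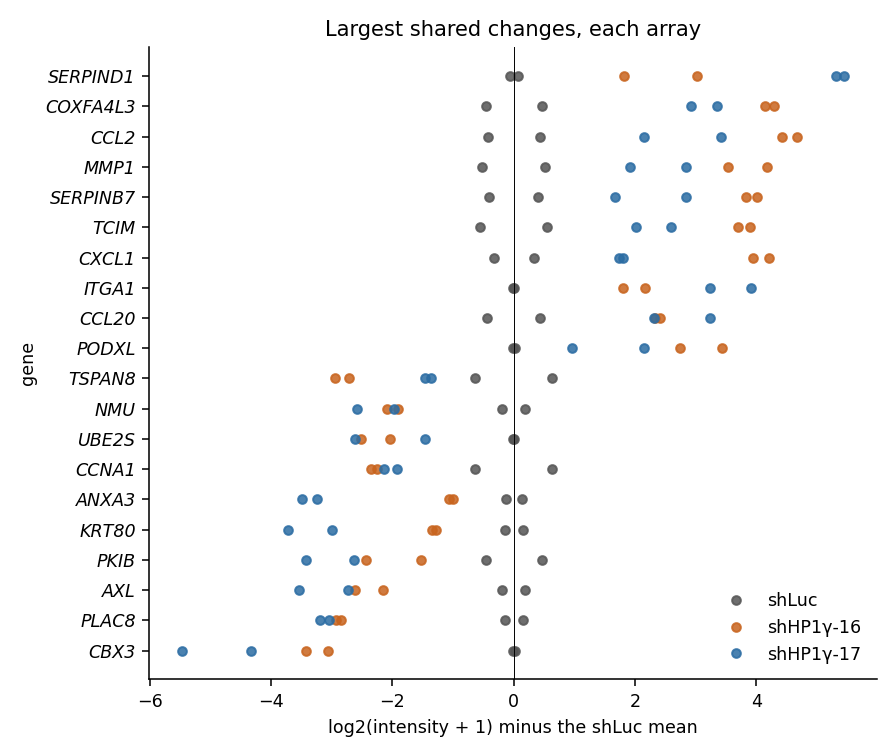
The log2(intensity + 1) of each array minus the shLuc mean is plotted for the 10 genes with the largest rises and the 10 with the largest falls, 1 point per array and 2 arrays per group. All 4 knockdown arrays lie on the same side of both shLuc arrays for each gene, as the choice of genes required.

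NF-kappaB targets and cytokines, histone genes and interferon-stimulated genes were the lists that rose as groups over both shRNAs. The last of them passed with shHP1γ-17 and not with shHP1γ-16. Of 20 measured NF-kappaB targets and cytokines, 12 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.95, and all 20 were above 0 (camera adjusted p = 2.56e-12). The group's adjusted p = 0.183 with an estimated correlation, and by fry it was 0.0130. Beside CXCL1, CCL2 and CCL20, the adhesion molecule ICAM1 rose by 1.63 ± 0.20 (adjusted p = 0.00708). Of 9 histone genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 4.78e-06; adjusted p = 0.638 with an estimated correlation). Their largest calls were H2AC6 (1.74 ± 0.26), H4C8 (1.61 ± 0.36), H2BC5 (1.51 ± 0.19) and H2BC21 (1.41 ± 0.19). Without shLuc replicate 2 H4C8 had 1.04 (adjusted p = 0.179). Of 24 interferon-stimulated genes, 2 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0326; adjusted p = 0.421 with an estimated correlation). These were IFIT3 (1.13 ± 0.16, adjusted p = 0.0106) and IFIT2 (0.99 ± 0.19, adjusted p = 0.0253), both antiviral RNA-binding proteins. With shHP1γ-16 0 interferon-stimulated genes rose and 2 fell, with a median of -0.02 (camera adjusted p = 0.428), and with shHP1γ-17 the median was 0.62. IFIT2 had -0.24 with shHP1γ-16 and 2.22 with shHP1γ-17, and BST2, the antiviral tetherin, had -1.57 ± 0.39 (adjusted p = 0.0533). The interferon call was lost without shLuc replicate 1 (adjusted p = 0.180), shHP1γ-16 replicate 1 (0.0542) or shHP1γ-17 replicate 1 (0.0664), with the knockdown arrays as 1 group (0.302), and with the 5' to 3' ratio in the model (median 0.12, adjusted p = 0.431; IFIT3 0.74, IFIT2 0.56 and BST2 -0.78). The GAPDH ratio of 3' to 5' signal was 1.27 in shLuc and 3.38 and 1.80 in the knockdown groups.

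Cholesterol synthesis, mitotic, glycolytic, NRF2 and epithelial genes fell as groups over both shRNAs. Of these only the cholesterol list passed with each shRNA. The G2/M list had a median of -0.16 with shHP1γ-16 (camera adjusted p = 0.502), and with shHP1γ-17 the glycolysis list had -0.36 (0.198), the epithelial list -0.14 (0.0561) and the NRF2 list -0.02 (0.839, mean 0.07). Of 16 cholesterol synthesis genes, 0 rose and 6 fell (0 and 10 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.85e-06; adjusted p = 0.421 with an estimated correlation). The enzymes IDI1 (-1.17 ± 0.22, adjusted p = 0.0241), DHCR7 (-1.12 ± 0.21, adjusted p = 0.0236), EBP (-1.01 ± 0.18, adjusted p = 0.0203) and SQLE (-0.89 ± 0.17, adjusted p = 0.0240) fell. Of 24 G2/M and mitosis genes, limma called 0 (0 adjusted over the list alone), but 23 lay below 0, with a median of -0.62 (camera adjusted p = 5.05e-05; adjusted p = 0.941 with an estimated correlation). CENPA, the centromeric histone variant, had -0.83 ± 0.22 (adjusted p = 0.0582). The median was -0.24 without shHP1γ-17 replicate 1 and -0.98 without replicate 2. With the 5' to 3' ratio in the model this median turned to 1.01 and that of the NRF2 targets to 0.21. The cholesterol median was then -0.47, with EBP at -0.11 and DHCR7 at -0.52, and CENPA had 0.05. Of 21 glycolysis and hypoxia genes, 0 rose and 3 fell (3 and 8 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.00945; adjusted p = 0.638 with an estimated correlation). The fallen genes were the glycolytic enzymes ALDOC (-1.30 ± 0.28) and PGK1 (-0.58 ± 0.14) and the oxygen sensor EGLN3 (-0.84 ± 0.18). Without shLuc replicate 2 ALDOC had -0.79 (adjusted p = 0.116) and the cholesterol list a median of -0.53.

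Of 19 NRF2 targets, 0 passed, with a median of -0.28 (camera adjusted p = 0.00945; adjusted p = 0.941 with an estimated correlation), and the antioxidant reductase TXNRD1 had -0.57 ± 0.16 (adjusted p = 0.0678). Of 15 epithelial junction and keratin genes, 0 rose and 3 fell (0 and 6 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0110; adjusted p = 0.421 with an estimated correlation). They were the simple-epithelium keratins KRT8 (-1.43 ± 0.17, adjusted p = 0.00717), KRT19 (-1.15 ± 0.20, adjusted p = 0.0186) and KRT18 (-0.93 ± 0.18, adjusted p = 0.0251). The glycolysis call was lost without shLuc replicate 1 (adjusted p = 0.0596), the NRF2 call without shLuc replicate 1 (0.124) or shHP1γ-17 replicate 1 (0.0664), and the epithelial call without probe sets of the _x_at suffix (0.160) or with the 5' to 3' ratio in the model (median -0.06, adjusted p = 0.0777). With that ratio KRT18 had -0.14 and TXNRD1 -0.32. The epithelial median was -0.49 and -0.22 without shLuc replicates 1 and 2, and -0.22 and -0.06 without shHP1γ-16 replicates 1 and 2. In all, 8 of 26 tested lists shifted by camera (3 up and 5 down), against 0 with an estimated correlation (1 at an unadjusted p) and 1 by fry. The ACTB ratio of 3' to 5' signal was 1.96 in shLuc and 8.58 and 5.10 in the knockdown groups.

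Genes called within the remaining lists went both ways. Among YAP/TEAD targets 1 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.235), the falls including AXL and the matricellular genes CCN1 (-1.89 ± 0.23) and CCN2 (-1.50 ± 0.17). With shHP1γ-16 this list had 3 rises, 1 fall and a median of 0.27, and with shHP1γ-17 0 rises, 6 falls and -0.29. CCN1 had -4.13 with shHP1γ-17. It was lower by more than that (-4.47) with shHP1γ-17 than with shHP1γ-16, so it did not fall with shHP1γ-16. Among p53 targets 1 rose, MDM2, which encodes the p53 ubiquitin ligase (0.90 ± 0.14), and 3 fell, BAX (-0.91 ± 0.18), PLK2 (-0.85 ± 0.18) and PHLDA3 (-0.76 ± 0.14), with 2 and 3 adjusted over the list alone. In the BCL2 family the survival gene BCL2A1 (1.66 ± 0.18, from a shLuc intensity of 5.58 below the filter, and 0.74 with values raised to it) and the death-promoting gene BIK (1.59 ± 0.27) rose, and the death-promoting genes BAD (-0.89 ± 0.19) and BOK (-0.73 ± 0.17) fell, with 2 and 4 adjusted over the list alone. Of 21 genes of HP1 and H3K9 methylation, the methyltransferase gene EHMT1 (0.75 ± 0.17) and the remodeller gene ATRX (0.58 ± 0.14) rose, with 2 and 1 adjusted over the list alone. None of 23 measured KRAB zinc finger genes of chromosome 19 passed (median 0.03). Among mesenchymal genes COL5A1 rose (0.95 ± 0.20) and THBS1 (-1.47 ± 0.22) and TGFBI (-0.83 ± 0.14) fell, with 3 and 2 adjusted over the list alone. On their own, shHP1γ-16 gave 3 rises and 0 falls in this list and shHP1γ-17 gave 0 rises and 4 falls. THBS1 had -3.42 and TGFBI -2.15 with shHP1γ-17. Both were lower by more than that (-3.90 and -2.64) with shHP1γ-17 than with shHP1γ-16, so neither fell with shHP1γ-16. With the 5' to 3' ratio in the model BAX had -0.43, PLK2 -0.46, BAD -0.42, BIK 0.64, ATRX 0.37, COL5A1 0.39 and THBS1 -0.26.

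Among ERK pathway outputs the phosphatase gene DUSP4 rose (0.92 ± 0.21) and the transcription factor gene ETV4 fell (-1.38 ± 0.25), with 2 and 1 adjusted over the list alone, and with the 5' to 3' ratio in the model ETV4 had 0.16. DUSP4 had 0.61 without shLuc replicate 2 (adjusted p = 0.194). The chaperone gene HSP90B1 (-0.79 ± 0.19) was the only call among 20 genes of the unfolded protein and integrated stress response (0 adjusted over the list alone, and -1.44 with the ratio in the model), and ZBTB7A the only call among 10 corepressor complex genes (1 rose and 1 fell adjusted over the list alone). No gene was called, by limma or adjusted over the list alone, among the lists for DNA replication (median -0.07), lung epithelial lineage (-0.02), ribosome biogenesis (0.05), ribosomal proteins (-0.05), cancer-testis and germline genes (-0.05), clustered protocadherins (-0.02), DNA double-strand break repair (0.15) and splicing factors (-0.18). Of 11 fibroblast markers 1 rose and 1 fell, POSTN falling (-0.91 ± 0.14, from a shLuc intensity of 9649) and COL1A1 rising (0.63 ± 0.14, from 3467). COL1A1 had 1.32 ± 0.16 with shHP1γ-16 (adjusted p = 0.0627 and 0.0594 without its replicates 1 and 2) and -0.05 ± 0.16 with shHP1γ-17. COL1A2 (6182), LUM (939), COL3A1 (501), DCN (330) and PDGFRA (225) were measured in shLuc too, and FAP (29.7), PDGFRB (27.0) and THY1 (20.4) were dim. DCN had 1.03 (adjusted p = 0.183) over both shRNAs, and with shHP1γ-17 COL3A1 had 0.96 (adjusted p = 0.0150) and PDGFRA 1.27 (adjusted p = 0.0384). COL3A1 missed the threshold without shLuc replicate 2 or either shHP1γ-17 array, and PDGFRA in every leave-one-out fit but that without shHP1γ-17 replicate 2, at adjusted p from 0.0510 to 0.170. The 3 kept genes each of the leukocyte and endothelial markers, too few to test, had 0 calls. The signs of the median, the mean and camera differed for corepressors, p53 targets, the BCL2 family, ribosome biogenesis and protocadherins, none of them shifted. Of the calls of named genes in all comparisons, those lost numbered 13 without shLuc replicate 1, 30 without shLuc replicate 2, 26 and 32 without shHP1γ-16 replicates 1 and 2, and 15 and 11 without shHP1γ-17 replicates 1 and 2.

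**Figure D4:**
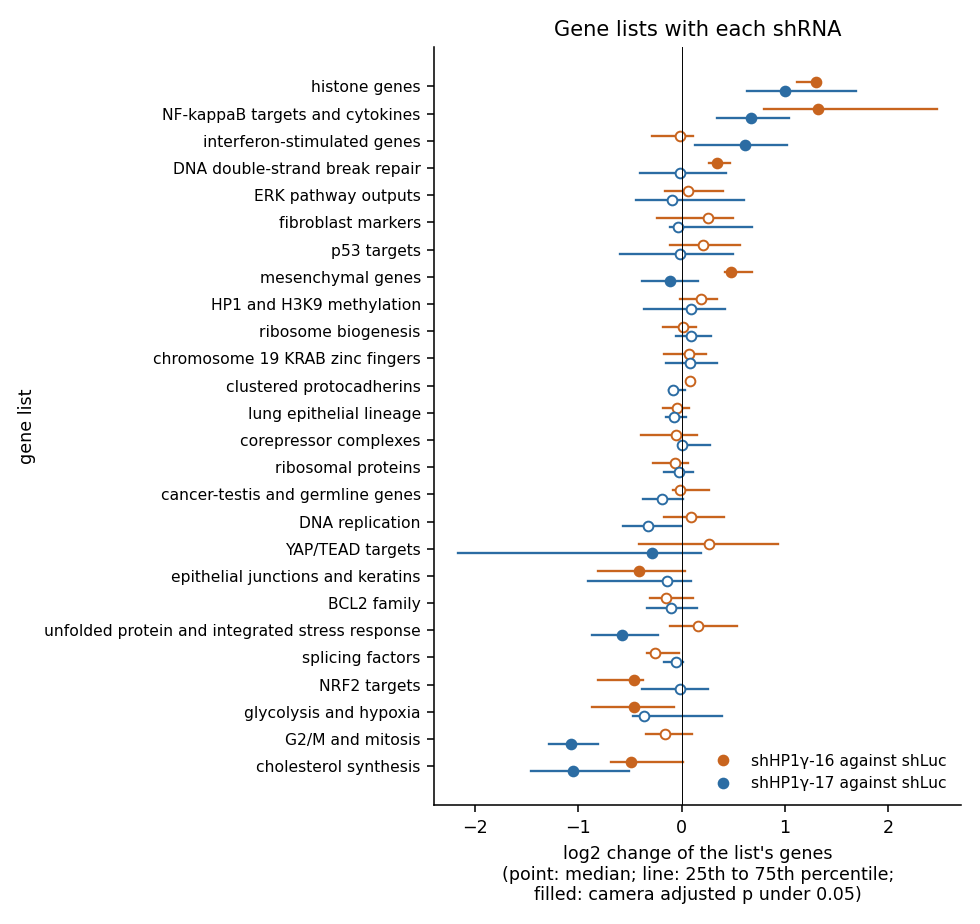
The log2 change of each list's genes is plotted per shRNA against shLuc, with a point at the median, a line from the 25th to the 75th percentile, and a filled point where camera's adjusted p was under 0.05. The NF-kappaB and histone lists lie above 0 with both shRNAs, and the G2/M list has a median of -0.16 with shHP1γ-16 and -1.07 with shHP1γ-17.

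Genes that passed the same way with each shRNA on its own numbered 315, of which 201 rose and 114 fell. They include all 20 genes named above as the largest rises and falls, which the rule for naming required. Among these are SERPIND1 (2.42 ± 0.34 with shHP1γ-16 and 5.37 ± 0.34 with shHP1γ-17), PLAC8 (-2.90 ± 0.17 and -3.12 ± 0.17) and AXL (-2.39 ± 0.30 and -3.14 ± 0.30). A further 42 genes passed in opposite directions. Independent lists of these sizes would share 59.6 genes the same way, and unchanged groups set against the same shLuc arrays shared 0.05 on average and 1 at most in 100 simulations. Across genes, which are not independent replicates, the changes with each shRNA correlated at r = 0.356 (rho 0.321), against 0.499 in the simulation, with a covariance of 0.0929 against 0.0233, a difference of 0.0696. The sign was the same for 60.9% of genes, against 66.6% in the simulation. The simulated groups held no real change, so their near-empty overlap was set in advance. It does not bound the part of the overlap that comes from the shared control. A split of the controls would leave 1 shLuc array on each side and was not made, so part of the overlap may come from the shared control. The number of shared genes was 137 without shLuc replicate 2, 48 and 30 without shHP1γ-16 replicates 1 and 2, 148 without shHP1γ-17 replicate 1 and 187 with each shRNA fitted only with shLuc. In every leave-one-out fit, 15 of the 315 passed, CBX3, PLAC8, SERPIND1, COXFA4L3, CCL2, CXCL1 and TCIM among them, and all 315 kept their signs.

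**Figure D5:**
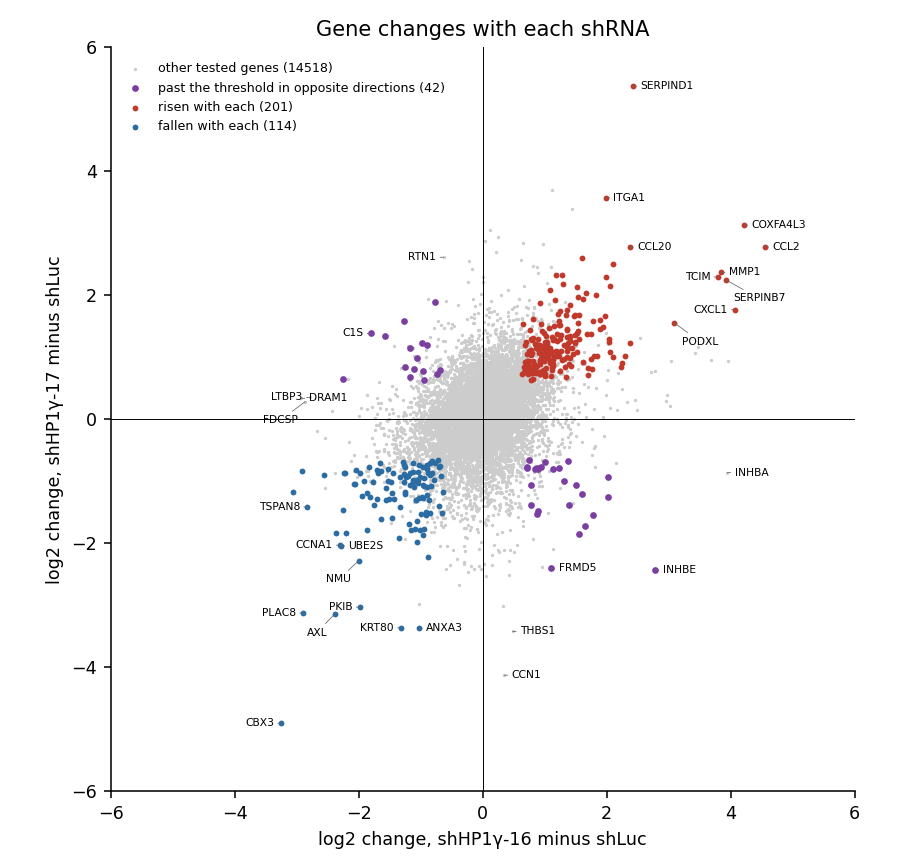
Each point is a gene, with its log2 change with shHP1γ-16 on the horizontal axis and with shHP1γ-17 on the vertical axis, both against shLuc. Coloured points passed with each shRNA, 201 upward, 114 downward and 42 in opposite directions.

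With shHP1γ-16 alone, CCL2 rose by 4.55 ± 0.42 (adjusted p = 0.00288), COXFA4L3 by 4.22 ± 0.30 (0.00222) and CXCL1 by 4.07 ± 0.24 (0.00146). SCG5, a chaperone of neuroendocrine secretory granules, rose by 3.96 ± 0.33 (adjusted p = 0.00288), and INHBA, the chain of the growth factor activin A, by 3.94 ± 0.30 (0.00273). Beside CBX3 and PLAC8, the water and glycerol channel gene AQP3 (-3.06 ± 0.28, adjusted p = 0.00288), the lysosomal gene DRAM1 (-2.93 ± 0.18, adjusted p = 0.00146) and MYEF2 (-2.92 ± 0.21, adjusted p = 0.00222) fell most. NF-kappaB targets rose as a group (13 of 20 rose and 0 fell, 17 and 0 adjusted over the list alone, median 1.32, camera adjusted p = 3.77e-13), with adjusted p = 0.167 with an estimated correlation. Histone genes (4 of 9 rose, 8 adjusted over the list alone, median 1.30, camera adjusted p = 9.92e-06) had adjusted p = 0.653 with an estimated correlation. Mesenchymal genes (3 of 17 rose, COL5A1 among them at 1.65 ± 0.23, 4 adjusted over the list alone, median 0.48, camera adjusted p = 8.46e-05) also had 0.653 as their adjusted p with an estimated correlation. Genes of DNA double-strand break repair had 0 calls, 17 of 18 above 0 and a median of 0.34 (camera adjusted p = 0.0197; adjusted p = 0.804 with an estimated correlation). That call was lost without shLuc replicate 2 (median 0.13, adjusted p = 0.426) or shHP1γ-16 replicate 2 (0.106), and the median was 0.53 without shLuc replicate 1 and 0.64 with the 5' to 3' ratio in the model. COL5A1 missed the threshold without shHP1γ-16 replicate 1 (adjusted p = 0.0784) or 2 (0.0813), and with the ratio in the model it had 0.91 and the mesenchymal median was 0.32.

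NRF2 targets fell as a group with shHP1γ-16 (2 of 19 fell, 8 adjusted over the list alone, median -0.46, camera adjusted p = 1.00e-05; adjusted p = 0.653 with an estimated correlation). PGD, an enzyme of the pentose phosphate pathway, was among them (-1.52 ± 0.37, but 0.25 with the 5' to 3' ratio in the model). Glycolysis and hypoxia genes (4 of 21 fell, 1 rose and 8 fell adjusted over the list alone, median -0.47, camera adjusted p = 0.00367; adjusted p = 0.653 with an estimated correlation) fell as a group, with the glycolytic enzymes ALDOC (-1.60 ± 0.32) and ALDOA (-1.34 ± 0.24). Epithelial genes (1 rose and 2 of 15 fell, 1 and 5 adjusted over the list alone, median -0.41, camera adjusted p = 0.0212; adjusted p = 0.653 with an estimated correlation) also fell, with KRT19 (-2.43 ± 0.23) and KRT8 (-2.04 ± 0.20). Cholesterol synthesis genes (1 of 16 fell, EBP at -1.04 ± 0.21, 4 adjusted over the list alone, median -0.49, camera adjusted p = 0.0212) had adjusted p = 0.804 with an estimated correlation. The cholesterol call was lost without shLuc replicate 2 (median -0.23, adjusted p = 0.426) or shHP1γ-16 replicate 1 (0.145), with a median of -0.77 without shLuc replicate 1. The epithelial call was lost without shLuc replicate 2 (median -0.23, adjusted p = 0.110) or shHP1γ-16 replicate 2 (0.0999). The glycolysis median was -0.27 without shLuc replicate 1 and -0.29 without shHP1γ-16 replicate 1. With the 5' to 3' ratio in the model the cholesterol (-0.18), epithelial (0.14) and NRF2 (0.12) calls were lost, at adjusted p of 0.177, 0.177 and 0.743, and EBP had 0.15. KRT8 and KRT19 passed in all 6 leave-one-out fits. PGD and EBP missed the threshold without either shLuc or either shHP1γ-16 array, ALDOC without shLuc replicate 2 or either shHP1γ-16 array, and ALDOA without either shHP1γ-16 array, at adjusted p up to 0.240. In all 1143 genes passed, of which 560 rose and 583 fell, and the 10 named genes kept their calls in all 6 leave-one-out fits. The count was 530 without shLuc replicate 2, 159 and 75 without shHP1γ-16 replicates 1 and 2, and with the 5' to 3' ratio in the limma model 0 (357 at an unadjusted p under 0.05). Standard errors then grew by a median factor of 3.50, and the changes correlated with those without it at 0.580. DRAM1 was -2.88 ± 0.66 and INHBA 3.03 ± 0.95. The 5' probe sets of GAPDH and ACTB were lower with shHP1γ-16 by log2 changes of -1.61 and -1.86, and the 3' probe sets had -0.20 and 0.25.

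With shHP1γ-17 alone, CCN1 (-4.13 ± 0.26, adjusted p = 0.000879) and THBS1, the matrix protein thrombospondin (-3.42 ± 0.26, adjusted p = 0.00114), fell most beside CBX3, ANXA3 (-3.37 ± 0.18) and KRT80 (-3.36 ± 0.25, or -3.02 with values raised to the filter). SERPIND1 rose by 5.37 ± 0.34 (adjusted p = 0.000879), or 4.66 with its shLuc values raised to the filter, and the epithelial transcription factor gene EHF by 3.70 ± 0.39 (0.00326). ITGA1 (3.58 ± 0.25), the chemokine gene CCL5 (3.39 ± 0.47, adjusted p = 0.00659) and COXFA4L3 (3.13 ± 0.30) rose as well. Interferon-stimulated genes rose as a group (9 of 24 rose and 0 fell, 13 and 2 adjusted over the list alone, median 0.62, camera adjusted p = 8.15e-05; adjusted p = 0.372 with an estimated correlation), among them IFIT2 (2.22 ± 0.22), IFIT3 (1.72 ± 0.19) and IRF7, a transcription factor of the interferon response (1.44 ± 0.21). NF-kappaB targets rose too (7 of 20 rose and 0 fell, 8 and 0 adjusted over the list alone, median 0.67, camera adjusted p = 6.79e-05; adjusted p = 0.372 with an estimated correlation), with ICAM1 at 2.36 ± 0.23. Histone genes rose as a group (4 of 9 rose, 5 adjusted over the list alone, median 0.99, camera adjusted p = 0.000482), with adjusted p = 0.611 with an estimated correlation and a median of 0.60 without shHP1γ-17 replicate 2.

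All 24 G2/M and mitosis genes were below 0 with shHP1γ-17 (3 fell, 11 adjusted over the list alone, median -1.07, camera adjusted p = 2.66e-08; adjusted p = 0.611 with an estimated correlation). Among them were PRC1, a spindle midzone protein (-1.54 ± 0.36), the checkpoint kinase gene BUB1 (-1.43 ± 0.37) and CENPA (-1.31 ± 0.25). The size rested on shHP1γ-17 replicate 1. Without it the list median was -0.36, PRC1 -0.93 (adjusted p = 0.0852), BUB1 -0.79 (0.120) and CENPA -0.93 (0.0609), without replicate 2 the median was -1.68, and with the 5' to 3' ratio in the model it was -0.06 and the call was lost (adjusted p = 0.645), with PRC1 at -0.60, BUB1 at -0.47 and CENPA at -0.71. PRC1 and BUB1 also missed the threshold without either shLuc array, and without either shHP1γ-16 array, where only the shared spread changed. CENPA missed it without shLuc replicate 2. Genes of the unfolded protein and integrated stress response (1 of 20 rose and 4 fell, 1 and 8 adjusted over the list alone, median -0.58, camera adjusted p = 0.000187; adjusted p = 0.611 with an estimated correlation) fell as a group, with ATF4 at -0.79 ± 0.16. Mesenchymal genes (4 of 17 fell, also 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0389; adjusted p = 0.611 with an estimated correlation) fell too, with TGFBI at -2.15 ± 0.16. Cholesterol synthesis genes fell (9 of 16, 12 adjusted over the list alone, median -1.05, camera adjusted p = 9.49e-08), with IDI1 at -1.66 ± 0.26, and had adjusted p = 0.429 with an estimated correlation. YAP/TEAD targets fell (6 of 15, also 6 with 1 risen adjusted over the list alone, median -0.29, camera adjusted p = 0.00278; adjusted p = 0.544 with an estimated correlation). The mesenchymal call was lost without shLuc replicate 2 (median -0.01, adjusted p = 0.164) or shHP1γ-17 replicate 2 (0.106), with a median of -0.23 without shLuc replicate 1 and -0.27 with the ratio in the model. The stress response median was -0.34 without shLuc replicate 2, and ATF4 passed in the leave-one-out fits only without shLuc replicate 1, with adjusted p from 0.0556 to 0.0834 in the others. The YAP/TEAD median was -0.47 without shHP1γ-17 replicate 1, -0.11 without replicate 2 and -0.73 with the ratio in the model. In all 1558 genes passed, of which 938 rose and 620 fell, and the 10 named genes kept their calls in all 6 leave-one-out fits. The count was 820 without shLuc replicate 2, 832 without either shHP1γ-16 array, 572 without shHP1γ-17 replicate 1 and 2 with the 5' to 3' ratio in the model. Changes with and without it correlated at 0.854, and standard errors grew by a median factor of 2.02. CCN1 was -4.36 ± 0.50 and ITGA1 3.18 ± 0.45 with it. The 5' probe sets of GAPDH and ACTB were lower with shHP1γ-17 by -0.47 and -1.36, and the 3' probe sets had 0.03 and -0.08.

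The shRNAs were also compared with each other, which tests differences between them directly. Lower with shHP1γ-17 than with shHP1γ-16 were INHBE, which encodes an inhibin beta chain, by -5.21 ± 0.37 (adjusted p = 0.000638) and INHBA by -4.80 ± 0.30 (0.000482), as were CCN1 (-4.47 ± 0.26, adjusted p = 0.000482), THBS1 (-3.90 ± 0.26, adjusted p = 0.000484) and FRMD5 (-3.51 ± 0.22, adjusted p = 0.000482). The intensity of INHBE with shHP1γ-17 (8.56) lay below the filter of 11.7, and with values raised to the filter the difference was -4.80. INHBE rose with shHP1γ-16 (2.78 ± 0.37) and fell with shHP1γ-17 (-2.43 ± 0.37). Higher with shHP1γ-17 were DRAM1 (3.27 ± 0.18), the reticulon gene RTN1 (3.25 ± 0.18), the complement protease gene C1S (3.20 ± 0.18), the secreted peptide gene FDCSP (3.15 ± 0.26) and LTBP3, which encodes a latent TGF-beta binding protein (3.14 ± 0.33), with adjusted p between 0.000482 and 0.00206. C1S fell with shHP1γ-16 (-1.81 ± 0.18) and rose with shHP1γ-17 (1.39 ± 0.18).

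As groups, interferon-stimulated genes (12 of 24 higher, 14 adjusted over the list alone, median 0.73, camera adjusted p = 7.90e-06; adjusted p = 0.326 with an estimated correlation) and NRF2 targets (5 of 19 higher, 6 adjusted over the list alone, median 0.67, camera adjusted p = 0.000542; adjusted p = 0.562 with an estimated correlation) were higher with shHP1γ-17. Lower were mesenchymal genes (9 of 17, 10 adjusted over the list alone, median -0.72, camera adjusted p = 2.69e-06; adjusted p = 0.396 with an estimated correlation) and G2/M genes (4 of 24, 9 adjusted over the list alone, median -0.97, camera adjusted p = 2.69e-06; adjusted p = 0.735 with an estimated correlation). YAP/TEAD targets (1 of 15 higher and 8 lower, also 1 and 8 adjusted over the list alone, median -1.0, camera adjusted p = 6.98e-06) and NF-kappaB targets (1 of 20 higher and 10 lower, 3 and 12 adjusted over the list alone, median -0.71, camera adjusted p = 0.000663) were lower, both with adjusted p = 0.388 with an estimated correlation. The stress response list (8 of 20 lower, 9 adjusted over the list alone, median -0.59, camera adjusted p = 3.80e-05) and cholesterol synthesis genes (5 of 16 lower, 6 adjusted over the list alone, median -0.47, camera adjusted p = 0.00139) had adjusted p = 0.562 with an estimated correlation. DNA replication genes (1 of 24 higher and 2 lower, 1 and 1 adjusted over the list alone, median -0.42, camera adjusted p = 0.0471) had adjusted p = 0.950 with an estimated correlation. The DNA replication call was lost without either shLuc array, where only the shared spread changed and the median stayed at -0.42. It was also lost without shHP1γ-16 replicate 2 (median -0.45). Without shHP1γ-17 replicate 1 the median turned to 0.13, against -0.96 without replicate 2. The G2/M median was -0.32 without shHP1γ-17 replicate 1 and -1.57 without replicate 2, and the NRF2 median 0.40 without replicate 2. With the 5' to 3' ratio in the model the NRF2 (0.36, adjusted p = 0.190) and stress response (-0.52, adjusted p = 0.0542) calls were lost, and the medians were -1.88 for G2/M, -1.22 for DNA replication and -0.65 for YAP/TEAD targets.

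Between the shRNAs 2211 genes differed, 1288 higher and 923 lower with shHP1γ-17, more than between either shRNA and shLuc (1143 and 1558). Without shHP1γ-16 replicate 1 or 2 fewer differed than between shHP1γ-17 and shLuc. Those fits leave 1 array on the shHP1γ-16 side, against 2 on each side of the other comparison, so they do not test the order. Without either shHP1γ-17 array, which both counts lose alike, more genes still differed between the shRNAs. The 10 genes named for this comparison kept their calls in all 6 leave-one-out fits, and the first principal component (45.2% of the variance) separated shHP1γ-17 from shHP1γ-16. The count was 1171 without shHP1γ-17 replicate 1 and 1 with the 5' to 3' ratio in the model. Differences with and without it correlated at 0.898, and standard errors grew by a median factor of 1.98. INHBA was -4.35 ± 0.54 and C1S 3.25 ± 0.38 with it. The ratio of 3' to 5' signal was higher with shHP1γ-16 than with shHP1γ-17 for GAPDH (3.38 and 1.80), ACTB (8.58 and 5.10) and dap (14.1 and 5.29).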

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

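The share of differing genes with the larger change and the fit with the 5' to 3' ratio were tests chosen only after the result was seen.

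More genes differed between the shRNAs (2211) than between either shRNA and shLuc (1143 and 1558). This order turned without either shHP1γ-16 array. Such a fit leaves 1 array on the shHP1γ-16 side of the comparison between the shRNAs. It touches that of shHP1γ-17 with shLuc only through the shared spread, though that count fell too. These fits therefore do not test the order. The order held without either shHP1γ-17 array, which both comparisons lose alike. A deeper loss of CBX3 with shHP1γ-17, where its log2 level was lower by a further -1.65, would make most differing genes change further with that shRNA. The larger change was with shHP1γ-17 for 56.2% of them, against 52.1% of all tested genes, which argues against dose as the main cause. Of the differing genes 68.8% had opposite signs against shLuc, while 60.9% of all tested genes had the same sign. Choosing genes that differ favours opposite signs, and 891 of the 2211 passed with neither shRNA, so this share decides nothing. Effects of each shRNA on other transcripts, or differences in RNA quality, may account for more of the differences. With the 5' to 3' ratio in the model 1 gene differed, but standard errors grew by a median factor of 1.98, so the lost calls do not speak for RNA quality. The 10 named differences stayed about as large (INHBA -4.35 ± 0.54 after -4.80 ± 0.30, and a correlation of 0.898 across all tested genes), but they were picked as the largest. The G2/M median moved from -0.97 to -1.88 and the NRF2 median from 0.67 to 0.36. With 89.6% of the variance of the ratio between groups, this fit cannot decide for or against RNA quality.

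The mean ratio of 3' to 5' signal was higher in the knockdown groups, for GAPDH 3.38 with shHP1γ-16 and 1.80 with shHP1γ-17, for ACTB 8.58 and 5.10, and for dap 14.1 and 5.29, while for phe (4.20 and 3.09) an shHP1γ-17 array lay below a shLuc array. The 25th percentile of the rises with shHP1γ-16 was 0.86, against a largest shift of 0.25 in a 3' control probe set, but the smallest rise that passed was 0.63, so the threshold fixed this outcome and signal loss stays open for the rises. For the falls with shHP1γ-16, the difference between the shHP1γ-17 arrays, with ratios of 6.88 and 3.32 for ACTB and 2.02 and 1.57 for GAPDH but 5.20 and 5.38 for dap and 2.69 and 3.49 for phe, was 0.0159 above that of matched lists, within their range, so this explanation stays open. With the ratio in the model the NF-kappaB median was 1.09 and the cholesterol synthesis median -0.47, while the G2/M median turned from -0.62 to 1.01. Because dap and phe are bacterial control transcripts, their higher ratios with shHP1γ-16 may point to labelling rather than to RNA of the cells, which phe leaves open for shHP1γ-17, and 89.6% of the variance of the ratio lay between groups and the model cannot separate it from the knockdown.

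Genes past the threshold with each shRNA in opposite directions numbered 42. Among the shared genes, shHP1γ-17 minus shHP1γ-16 was 2.95 for SERPIND1, 1.59 for ITGA1, 1.42 for TSPAN8 and 0.81 for ZBTB7A. It was -1.08 for COXFA4L3, -1.77 for CCL2, -1.67 for SERPINB7, -1.49 for TCIM, -2.30 for CXCL1, -1.53 for PODXL, -2.04 for KRT80 and -2.34 for ANXA3. Among the genes named for the difference it was 3.27 for DRAM1, 3.25 for RTN1, 3.20 for C1S, 3.15 for FDCSP and 3.14 for LTBP3. It was -5.21 for INHBE, -4.80 for INHBA, -4.47 for CCN1, -3.90 for THBS1 and -3.51 for FRMD5. The list medians of that difference were -0.97 for G2/M and mitosis, -0.42 for DNA replication, 0.73 for interferon-stimulated genes, -0.71 for NF-kappaB targets and -0.72 for mesenchymal genes. They were -0.47 for cholesterol synthesis, -0.59 for the unfolded protein and integrated stress response, 0.67 for NRF2 targets and -1.0 for YAP/TEAD targets.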

How the results depend on the processing

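Genes changed by both shRNAs numbered 1144 and, with the 4 knockdown arrays as 1 group, 2. The pooled group then held the differences between the shRNAs as spread. Fitting only the groups compared gave 832 genes for shHP1γ-17 and 187 shared. Of the genes called, those at least 2-fold changed numbered 449 for both shRNAs, 655 for shHP1γ-16, 849 for shHP1γ-17, 1111 between the shRNAs and 151 shared. Of the 8 lists shifted, 0 passed with an estimated correlation and 1 by fry. With 1 array left out, the counts ranged from 182 (without shHP1γ-16 replicate 2) to 950 for both shRNAs, 75 to 1100 for shHP1γ-16, 572 to 1597 for shHP1γ-17, 365 to 2572 between the shRNAs and 30 to 403 shared, and 7 to 10 lists shifted. The CBX3 change ranged from -3.42 to -3.07 with shHP1γ-16 and from -5.46 to -4.34 with shHP1γ-17, past the threshold each time. Fewer arrays give fewer degrees of freedom, and the cause of the differences between left-out arrays was not tested.

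With the covariate for the 5' to 3' ratio, added after the data were seen, limma called 0 genes for both shRNAs, 0 for shHP1γ-16, 2 for shHP1γ-17, 1 between the shRNAs and 0 shared, against 378, 357, 1189 and 1842 at an unadjusted p under 0.05 in the first 4. Standard errors grew by a median factor of 3.09 for both shRNAs. The CBX3 change was -1.66 ± 0.92 with shHP1γ-16 and -4.09 ± 0.53 with shHP1γ-17. For both shRNAs the sign turned for ETV4 (0.16) among the called genes named and, among lists shifted in either fit, for G2/M and mitosis (1.01, adjusted p = 1.33e-07), DNA replication (1.01, adjusted p = 5.94e-09) and NRF2 targets (0.21, adjusted p = 0.326). With shHP1γ-16 it turned for ETV4 (-1.78 to 0.26), PGD (-1.52 to 0.25) and EBP (-1.04 to 0.15), and for the epithelial (-0.41 to 0.14, adjusted p = 0.177) and NRF2 lists (-0.46 to 0.12, adjusted p = 0.743). For ribosome biogenesis (median 0.42, adjusted p = 0.0180) camera's direction turned upward, with a median above 0 each time. Lists shifted then numbered 11 instead of 8. Gained beside DNA replication and ribosome biogenesis were HP1 and H3K9 methylation (0.56, adjusted p = 0.00322), the stress response (-0.53, adjusted p = 1.28e-05), YAP/TEAD targets (-0.57, adjusted p = 0.000149) and double-strand break repair (0.52, adjusted p = 0.0159), and lost were interferon-stimulated genes, NRF2 targets and epithelial genes. These list p-values came from camera at the preset correlation. The correlation estimated without the ratio was 0.933 for G2/M and mitosis and 0.866 for DNA replication. No p with an estimated correlation is given for the fit with the ratio. The log2 ratio was -1.90 on shHP1γ-17 replicate 1 and -1.19 on replicate 2. The G2/M median with shHP1γ-17 was -0.36 without replicate 1 and -1.68 without replicate 2. The cause, and how far the G2/M sign rests on this pair, was not tested.

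The replicate block gave 1073 genes for both shRNAs and changed no count by more than 1.5 times. Quantile normalization (1115), median centring (1075), no filter (1079), the mean of a gene's probe sets (773), leaving out probe sets of the _x_at suffix (1148), a trended robust variance (1122) and an offset of 16 (1037) also stayed within 1.5 times for both shRNAs. The splicing list passed with the mean of probe sets (adjusted p = 0.0282), and with an array left out the lists gained were the stress response, double-strand break repair, DNA replication and splicing.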

Other observations

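Among the 42 genes that passed with each shRNA in opposite directions, the following were chosen after their values were seen. TNFRSF11B, a decoy receptor for RANK ligand, had a log2 change of 1.78 with shHP1γ-16 and -1.54 with shHP1γ-17, PTX3, a soluble pattern recognition protein, 2.02 and -1.25, and GREM1, a BMP antagonist, 2.02 and -0.93. CDK6, a cell cycle kinase, had 1.65 and -1.72, and ADAM19, a membrane metalloprotease, 1.61 and -1.21. The other way round were TIMP1, an inhibitor of metalloproteases (-1.27 and 1.59), ID1, an inhibitor of helix-loop-helix factors (-2.25 and 0.65), and the interferon-stimulated gene IFI44L (-0.91 and 1.19).

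The tests of DNA replication genes and of histone probe sets were chosen only after the result was seen. Histone genes rose as a group over both shRNAs (median 1.24) by camera at the preset correlation, but not with an estimated correlation (camera adjusted p = 0.638). A larger share of cells in S phase may raise them, but the DNA replication list had a median of -0.33 with shHP1γ-17 and 0.09 with shHP1γ-16, and expression alone leaves this open. Probes shared between near-identical histone genes may make 1 change look like several, but the 4 probe sets without a shared-probe suffix had a median of 0.76 with shHP1γ-17 and 1.35 with shHP1γ-16, all above 0, which argues against this as the only source. Histone transcripts that gain a poly(A) tail would also give more signal, which was not tested here.

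As a hypothesis, loss of a chromatin protein may release neighbouring genes together. Of 14809 neighbouring pairs of tested genes, 44 had both genes risen over both shRNAs, against a mean of 28.9 in permutations (permutation p = 0.004), among them CXCL2 and CXCL3, MMP1 and MMP10, and IFIT2 and IFIT3. Pairs with unlike names numbered 33 against 27.4 (permutation p = 0.148), so related gene families may account for the excess. For fallen genes 24 pairs against 16.9 did not pass (permutation p = 0.0573), which does not show that there is no such grouping.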
